A study of Mus musculus with 6 samples.

How the data were processed

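The samples were migrating keratinocytes from mouse skin wounds harvested on day 3. Per the labels' protocols, diabetes had been induced with a diet rich in fat and fructose, started at 8 weeks of age and given for 16 weeks, and the normal animals received a control diet for the same period. Fixed and dehydrated tissue was sectioned, the leading keratinocytes of the epithelial tongue were located by E-cadherin staining and taken by laser capture, and the captured cells of a sample were pooled across its sections. Total RNA was extracted with a kit for fixed tissue and labelled with biotin using a whole-transcript kit for picogram inputs, per the labels' protocols. The group and replicate number of each array came from its title. The titles call the 3 arrays of a group biological replicates, but no label states that each came from a separate mouse, so p-values measure the spread between these samples.

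The deposited values were log2 probe set signals, 1 per probe set and array, for 35556 probe sets on 6 arrays. The base of the logarithm is not given in the sources used here and was taken from the values, since with base 10 or natural logarithms the brightest signals would exceed the range of a 16-bit scanner. Partek is named in the submitters' processing notes without a version, and the background correction, normalization and summarization are not given in the sources used here. Array medians over all probe sets lay between 1.75 and 1.80, and no further scaling was applied. The number of columns belonging to samples of other series was 0.

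Probe sets were named from the array's annotation table. It gave 1 gene symbol for 21789 probe sets and several symbols for 1621, and 12146 probe sets were not listed in it and stay unnamed here, with any control probe sets among them not told apart. Symbols were updated by gene ID through a mouse gene table of assembly GRCm38.p6, which matched 21698 of the single-gene probe sets. No coordinates are printed because the build of the probe annotation is not given in the sources used here. Probe sets naming several genes were left out of the gene test. For the 999 genes with several single-gene probe sets, the probe set with the highest mean over all arrays stood for the gene. This left 19938 genes, with no filter on dim genes.

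Diabetic and normal arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with group as the only term and Benjamini-Hochberg adjustment over all genes. Differences are given as diabetic minus normal on the log2 scale, with limma's moderated standard error (SE). Counts used an adjusted p under 0.05, and separately an unadjusted p under 0.05 with a fold of at least 1.5. Gene lists were tested with camera, a competitive test, using its preset correlation between genes of 0.01 and adjustment over the 32 lists with at least 5 measured members. Where the correlation was instead estimated, camera took its degrees of freedom from the arrays and not from the genes. With so few arrays this raises p by itself, whatever the correlation. The 33 lists held 926 places, of which 822 were measured, and the list of mitochondrially encoded RNAs had 0 measured members. Each list's median was also ranked among those of 10000 random lists of the same size matched on mean level in 50 bins.

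The groups, tests, gene lists, named genes and most alternatives were fixed before the data were examined. Named genes were 22 keratinocyte, wound and reference genes, whatever their values, of which 1 is not reported here. Added to these were up to 10 genes higher and 10 lower in diabetic samples. The rule asked for an adjusted p under 0.05, no overlap between the groups and a brighter group above the median of all genes, leaving out predicted genes, chemosensory receptors and small RNAs. No gene passed the adjusted threshold, so these places went to the smallest unadjusted p under the same conditions. For each list, up to 4 members with the smallest unadjusted p could be named. Alternatives covered between-array scaling, the variance model, array weights, filters on dim genes, the handling of several probe sets, a replicate block, each array left out in turn, other thresholds and other list tests.

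A detection check was chosen after the data were seen. On each array, the 95th percentile of 1194 olfactory and vomeronasal receptor genes, which skin is not known to express broadly, served as a background limit and lay between 1.98 and 2.12. It takes no account of the base composition of the probes, which can raise background and was not tested here because probe sequences were not used. A gene at or below the limit has no more than a bound on its level, and differences between signals near background can understate differences in RNA.

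The gene and list tests were checked on simulated data, in 20 draws of 19938 genes with 200 changed genes, 50 at each fold. Means were those of the arrays, each gene's variance was drawn from limma's prior, and noise was independent between genes. At an adjusted p under 0.05 the test recovered 42.5% of 1.5-fold changes, 94.2% of 2-fold changes and 100% of 4-fold and of 8-fold changes, with 8.8 false calls per draw on average. A list shifted by 0.30 was called in 100% of draws, with 0 false lists. These rates do not carry over to genes that vary more than the prior gives, or to genes that vary together. They also hold only for 200 changed genes per draw, as the adjusted threshold is harder to pass where fewer genes change. A lack of calls on the real arrays therefore does not show that 2-fold changes were absent. On the real arrays Rpl26 differed by 2.51 (SE 0.50) and did not pass (limma adjusted p 0.780). The precision of every comparison is limited by having 3 arrays per group.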

Results

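Gene expression was measured on whole-transcript arrays in keratinocytes captured from the migrating tip of the epithelium in mouse skin wounds, 3 days after wounding. Arrays of 3 samples from diabetic mice, whose diabetes was induced by diet, were compared with arrays of 3 samples from normal mice on a control diet. The comparison asks how the transcripts of re-epithelializing keratinocytes differ in diabetes. All values are log2 probe set signals, and differences are diabetic minus normal with n = 3 arrays per group.

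The arrays were dim. The median gene signal lay between 1.79 and 1.83 on each array, while the background limit set from chemosensory receptor genes lay between 1.98 and 2.12. Of 19938 genes, 3466 (17.4%) exceeded the limit on all 6 arrays and 10261 (51.5%) on none. The share of genes above the limit was 35.3%, 36.6% and 29.4% on the diabetic arrays and 27.4%, 28.4% and 28.7% on the normal arrays. The limit itself was lower on diabetic replicates 1 and 2 (1.98 and 2.01) than on the other 4 arrays. Correlations across genes, which are not independent replicates, ran from 0.907 to 0.920 among diabetic arrays, from 0.887 to 0.900 among normal arrays and from 0.877 to 0.914 between groups. The leading principal component held 25.1% of the variance. Its scores were -14.4, -7.12 and -4.41 for the diabetic arrays and 23.6, -3.58 and 5.87 for the normal arrays.

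No gene differed past the adjusted threshold between diabetic and normal keratinocytes. Signal for 7SK (Rn7sk, probe set 10426437), the RNA that restrains transcription elongation, was 7.31 ± 1.03 (SD) in diabetic and 5.25 ± 0.79 in normal samples, a difference of 2.06 (SE 0.47). The ribosomal protein gene Rpl26 (10377368) was at 6.66 ± 0.97 and 4.15 ± 1.02, a difference of 2.51 (SE 0.50), and its relative Rpl5 (10459669) was at 4.76 ± 0.60 and 3.03 ± 0.22, a difference of 1.74 (SE 0.26). The heat shock cognate chaperone gene Hspa8 differed by 1.73 (SE 0.66), and Krt8, a keratin of simple epithelia, by 1.19 (SE 0.45). The interferon-induced membrane protein gene Ifitm3 differed by 1.24 (SE 0.32), with diabetic arrays at 3.30, 1.78 and 3.29 and normal arrays between 1.37 and 1.68. These 6 belong to 11 genes with an unadjusted p under 0.05 and at least a 2-fold difference, all of them higher in diabetic samples (9 of 9 went 1 way in another split of the arrays). Of the 11, Rpl5, Rpl26 and Hspa8 were named by a rule fixed in advance that selects on p, so also through their values. The rest were picked out after their values were seen. Besides those 6, the 11 held the Y RNA gene Rny1 (2.01), the small nucleolar RNA gene Snord118 (1.86), the RNase MRP RNA gene Rmrp (1.52), Naca (1.23) and Baiap2l1 (1.19). Without diabetic replicate 1 the difference was 1.09 for Rny1, 1.09 for Snord118, 0.98 for Hspa8, 0.61 for Rmrp and 0.42 for Naca, and without diabetic replicate 2 it was 0.52 for Krt8 and 3.06 for Rny1.

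With limma and Benjamini-Hochberg adjustment, 0 of 19938 genes passed, the smallest adjusted p being 0.405. The ordinary linear model per gene without variance moderation also called 0. At an unadjusted p under 0.05 there were 1109 genes, 526 higher and 583 lower in diabetic samples, where chance alone gives 997. Adding a fold of at least 1.5 left 51 genes, 40 higher and 11 lower, against a median of 44 in simulated draws with no change. After quantile normalization the split was 32 higher and 15 lower. Without diabetic replicate 2, diabetic replicate 3, normal replicate 2 or normal replicate 3 that count was 85, 99, 109 or 90. The split also moved with the normal array left out, to 39 higher and 31 lower without normal replicate 1, 71 and 38 without normal replicate 2, and 47 and 43 without normal replicate 3. The values of the 3 diabetic and 3 normal arrays did not overlap for 2129 genes (10.7%), where chance gives 10%. The 95% confidence interval of the difference lay within 2-fold in either direction for 19855 genes (99.6%), a statement about array signal that does not bound differences in RNA for genes at background.

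Among the genes ranked by p that fulfilled the naming rule, the 10 higher in diabetic samples were led by Rpl5, Trio, a guanine nucleotide exchange factor, and Phlda1, a pleckstrin-homology-like protein. Trio differed by 0.96 (SE 0.16, adjusted p 0.405) and Phlda1 by 0.66 (SE 0.12, adjusted p 0.623). Next came Rpl26, the ubiquitin-ligase subunit gene Asb13 (0.65), the Rab GTPase-activating gene Tbc1d25 (0.53), Ube2j2 (0.70), the lysosomal membrane gene Laptm4a (0.59), Nkx1-1 (0.54) and Gdap1l1 (0.60). The other 4 probe sets of Rpl5 differed by 0.09, 0.51, 0.51 and 0.27, and the other probe set of Trio by 0.08, so the size rests on the brightest probe set in both genes. The 10 lower in diabetic samples were Cyp2c66 (-0.55), Wdr93 (-0.50), the forkhead gene Foxn2 (-0.62), Tex44 (-0.48), the ciliogenesis gene Fuz (-0.50), Tab3 (-0.46), an adaptor in TAK1 signalling, Strc (-0.46), the lysosomal chloride transporter gene Clcn7 (-0.45), Gpr137b-ps (-0.60) and Gga3 (-0.49). Of these 10, Foxn2, Fuz and Gpr137b-ps were above the background limit on all 6 arrays, and Cyp2c66 and Wdr93 on none. All 20 had an adjusted p of at least 0.405 in limma, and none is a call. Rpl5 passed without diabetic replicate 3 (difference 2.07, adjusted p 0.0109), and Ifitm3 (1.74, adjusted p 0.00348) and Snord118 (2.66, adjusted p 0.0447) passed without diabetic replicate 2.

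**Figure D1:**
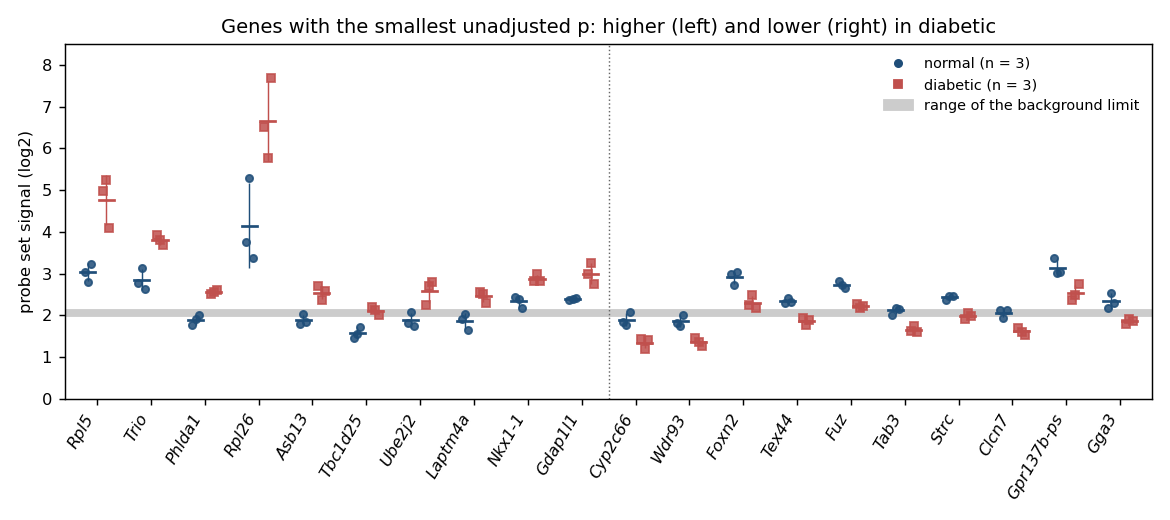
Probe set signal (log2, vertical axis) of the 10 genes higher and the 10 lower in diabetic samples with the smallest unadjusted p under the naming rule, with 1 point per array, horizontal bars for group means and vertical lines for ± 1 SD (n = 3). The grey band spans the background limit of the 6 arrays, 1.98 to 2.12, and Rpl5 and Rpl26 show the widest gaps, 1.74 and 2.51.

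Most of the keratinocyte genes fixed for naming were at or near background in both groups, and none passed. In the wider lists, 5 of 25 basal, 6 of 34 suprabasal and 6 of 31 wound-edge members were above the limit on all arrays. E-cadherin (Cdh1), used to locate the cells, was at 1.88 ± 0.04 in diabetic and 2.04 ± 0.03 in normal samples, under the limit on every array. The basal keratins Krt5 and Krt14 differed by 0.19 (SE 0.15) and 0.23 (SE 0.15), and the values of the groups overlapped for both genes. Trp63, the transcription factor of stratified epithelium, differed by -0.31 (SE 0.14, adjusted p 0.887). The wound-induced keratins Krt6a, Krt16 and Krt17 differed by -0.16, -0.26 and 0.06, and the suprabasal keratins Krt1 and Krt10 by 0.01 and -0.01.

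Other genes of wound keratinocytes chosen in advance likewise showed small differences in signal. They were -0.17 for the gelatinase gene Mmp9, -0.15 for the urokinase gene Plau, 0.10 for the integrin gene Itga5, 0.04 for Itgb1, 0.05 for the EGFR ligand gene Hbegf and less than 0.01 in size for Fosl1 and S100a8. Il1b differed by -0.23 (SE 0.11, adjusted p 0.893) and the proliferation marker Mki67 by 0.11 (SE 0.14). The glucose transporter gene Slc2a1 differed by 0.09 and the insulin receptor gene Insr by -0.01. Collagen Col1a1, a fibroblast gene, was at 3.80 ± 0.39 and 3.50 ± 0.15, a difference of 0.30 (SE 0.20), which was 0.52 without diabetic replicate 1 and 0.13 without diabetic replicate 2. Col1a1, Hbegf and Krt10 were the only fixed genes above the limit on all 6 arrays, and 10 of the 21 measured were above it on none. Adjusted over the list alone, 0 of the 21 passed, with a smallest adjusted p of 0.389 in limma. The confidence interval lay within 2-fold for all 21 and within 1.5-fold for 19. For the genes at background these intervals describe array signal and do not bound differences in RNA.

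**Figure D2:**
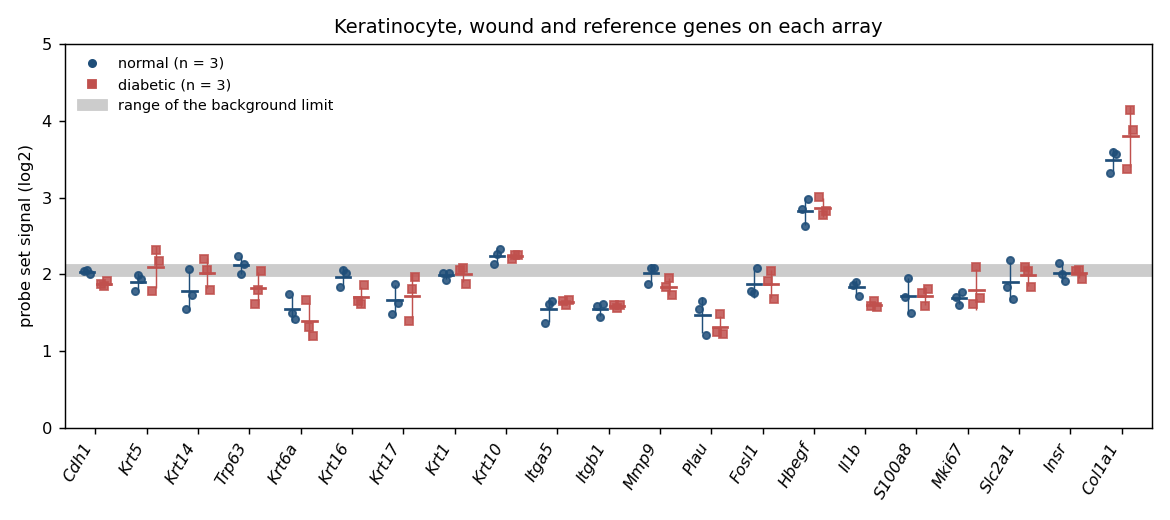
Probe set signal (log2, vertical axis) of the 21 measured genes fixed in advance, with 1 point per array, horizontal bars for group means and vertical lines for ± 1 SD (n = 3). The grey band spans the background limit of the 6 arrays, 1.98 to 2.12, and most keratinocyte genes lie in or under it in both groups while Col1a1 (3.80 and 3.50) and Hbegf (2.87 and 2.82) lie above.

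Ribosomal protein genes, a list fixed to follow RNA quality, passed camera with higher signal in diabetic samples (adjusted p = 0.00490), but not with an estimated correlation (adjusted p = 0.421 with an estimated correlation). That estimate was -0.011, under the preset 0.01, so correlation between members does not account for the higher p. The fewer degrees of freedom used with an estimated correlation raise it. Of 27 measured members 18 were higher and 9 lower, with a median difference of 0.11. The 4 with an unadjusted p under 0.05 were all higher, namely Rpl5, Rps19 (0.92, SE 0.31), Rps18 (0.72, SE 0.23) and Rpl27 (0.39, SE 0.15). Rpl5, Rps18 and Rpl27 had 5, 7 and 4 probe sets, and their values are those of the brightest alone. Rps19 was at 3.45, 4.85 and 3.99 on the diabetic and 3.10, 2.83 and 3.60 on the normal arrays, so its size leans on diabetic replicate 2. Adjusted over the list alone 1 member passed, Rpl5. Rplp1 and Rpl14 differed by -0.41 and -0.47. A wider set, chosen after the data were seen, took all 68 measured genes with symbols of the Rpl and Rps pattern. That pattern also admits genes that are not ribosomal proteins, such as the Rps6ka kinases. The median difference of this set was 0.02, with 6 higher and 3 lower at an unadjusted p under 0.05. The list's camera adjusted p was 0.0355 with the mean of each gene's probe sets. It was 0.155 without normal replicate 3, 0.0743 in rank-based camera and 0.300 in fry, which tests a list against no change instead of against other genes.

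Skeletal muscle genes, a list fixed as markers of another cell type near the wound edge, also passed camera with higher signal in diabetic samples (adjusted p = 0.0226), but not with an estimated correlation (adjusted p = 0.443 with an estimated correlation). Of 22 members 17 were higher and 5 lower, with a median difference of 0.11. The myosin gene Myh2 differed by 0.35 (SE 0.12), Myot by 0.27 (SE 0.11), the light chain gene Mylpf by 0.30 (SE 0.15) and the troponin gene Tnni2, at 3.49 ± 0.12 and 3.26 ± 0.11, by 0.23 (SE 0.15). Myh2 was above the background limit on 1 diabetic and 0 normal arrays and Myot on none, while Mylpf and Tnni2 were above it on every array. Adjusted over the list alone 0 passed. The list's adjusted p was 0.351 without diabetic replicate 1, 0.0872 without normal replicate 1, 0.155 without normal replicate 3, 0.0742 after quantile normalization, 0.0568 without the dimmer 50% of genes, 0.361 among genes above the background limit, 0.0610 in rank-based camera and 0.300 in fry.

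No keratinocyte list passed. Among 25 basal keratinocyte and adhesion genes 14 were higher and 11 lower (camera adjusted p 0.921), with Dsp at -0.30, Perp at -0.25 and Jup, the plakoglobin gene, at 0.25. Among 31 wound-edge activation genes 11 were higher and 20 lower (adjusted p 0.411), with Krt6b at -0.48 (SE 0.29), Itga2 at -0.27 and the stromelysin gene Mmp3 at 0.27. Single arrays carried most of 2 of these, Krt6b at 2.21, 3.28 and 1.76 on the normal arrays and Mmp3 at 1.58, 1.41 and 2.05 on the diabetic arrays. Of 34 suprabasal and terminal differentiation genes 24 were higher (adjusted p 0.589), and the cornified envelope genes Lce1b and Lce1c differed by -0.40 and 0.34. Diabetic replicate 1 carried most of the Lce1c difference, at 2.19 against 1.54 and 1.53 on the other diabetic arrays. Of 43 actin cytoskeleton and migration genes 30 were higher (adjusted p 0.231), with Tpm3 at 0.54 (SE 0.17), Myl9 at 0.34, Tln1 at 0.26 and Rhob at -0.33. Of 35 cell cycle genes 14 were higher and 21 lower (adjusted p 0.921), with Ccnb2 at 0.40 and Prc1 at -0.32. The mesenchymal transition list had 14 of 25 members higher (adjusted p 0.666), led by Snai1, a repressor of E-cadherin, at 0.53 (SE 0.17). Matrix remodelling genes were split 17 higher and 16 lower (adjusted p 0.986). The same diabetic samples carried the higher ribosomal protein and skeletal muscle signal given above.

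Inflammatory and signalling lists did not pass either. Of 35 cytokine and chemokine genes 15 were higher and 20 lower (camera adjusted p 0.689), with Tnf at -0.46 (SE 0.12), above the background limit on all 3 normal and 0 diabetic arrays, Cxcl2 at -0.71 (SE 0.32) and Il1a at 0.33. Much of the Cxcl2 difference rests on normal replicate 2, with normal arrays at 1.97, 3.39 and 1.80 and diabetic arrays between 1.54 and 1.79. For Il1a the diabetic arrays were at 2.06, 1.53 and 1.62 and the normal arrays between 1.36 and 1.47. The antimicrobial list had 10 higher and 12 lower (adjusted p 0.561), with Defb4 at -0.36 and Saa1 at -0.38, both under the limit on all arrays. The interferon list had 14 higher and 16 lower (adjusted p 0.702), with Mx2 at -0.41 and Tap1 at 0.27. Among 29 AP-1 and immediate early genes 16 were higher (adjusted p 0.986), with Fosb at 0.36, Junb at -0.29, Ier3 at -0.35 and the MAP kinase phosphatase gene Dusp4 at -0.46. EGFR and growth factor receptor genes had 17 of 28 higher (adjusted p 0.971), with Igf1 at -0.39 and Igf1r at 0.25. Wnt and Notch genes had 19 of 27 higher (adjusted p 0.231), with Wnt10a at 0.35 and the NF-kappaB inhibitor gene Nfkbia at 0.51 (SE 0.14). The p53, apoptosis and senescence list had 15 of 23 higher (adjusted p 0.530), with Sesn2 at 0.26.

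Metabolic lists, chosen because the animals were diabetic, showed no shift past the threshold. Of 32 insulin signalling and glucose uptake genes 18 were higher and 14 lower (camera adjusted p 0.702), with Akt2 at 0.36 (SE 0.15) and the insulin-responsive transporter gene Slc2a4 at -0.34. Glycolysis and hypoxia genes had 10 higher and 12 lower (adjusted p 0.986), with Bnip3 at -0.38 and Egln3 at 0.31. Oxidative phosphorylation had 28 of 45 higher (adjusted p 0.548), with Ndufb8 at 0.53 and Cox5a at -0.28. The NRF2 list had 19 of 30 higher (adjusted p 0.820), with Ftl1 at -0.35. Cholesterol and fatty acid synthesis had 16 of 25 higher (adjusted p 0.356), with the sterol regulator Srebf2 at 0.29 and the squalene epoxidase gene Sqle at 0.36 (SE 0.20). The groups overlapped for Sqle, at 2.00, 2.71 and 2.10 on the diabetic and 1.63, 2.23 and 1.85 on the normal arrays. Fatty acid oxidation had 11 higher and 13 lower (adjusted p 0.841), with Ppargc1a at -0.32. The unfolded protein and heat shock list had 14 higher and 14 lower (adjusted p 0.841), with Hspa8 the only member with an unadjusted p under 0.05.

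Markers of other cells in wounded skin gave no further call. Fibroblast genes had 12 of 19 members higher and endothelial and pericyte genes 10 of 18, both at a camera adjusted p of 0.530. Neutrophil genes had 4 higher and 12 lower, with Trem1 at -0.48 (SE 0.16), and macrophage and monocyte genes 9 higher and 11 lower, both at an adjusted p of 0.561. Langerhans and T cell genes had 8 higher and 7 lower and adipocyte genes 11 higher and 3 lower, both at an adjusted p of 0.666. Hair follicle and sebaceous gland genes had 11 higher and 13 lower (adjusted p 0.986). Among them the hair follicle transcription factor gene Foxn1 was at 0.51 (SE 0.13), the only member passing adjusted over the list alone (0.0436 in limma), and Krt25 was at -0.46. Foxn1 was above the background limit on 1 diabetic and 0 normal arrays, and its p was not adjusted over the 32 lists. The lists of melanocyte, Schwann and mast cell genes (adjusted p 0.841) and of red blood cell and platelet genes (adjusted p 0.767) had 6 of 15 and 3 of 6 members higher. Apart from Rpl5 and Foxn1, 0 members of the 32 lists passed adjusted over the list alone, and with an estimated correlation 0 lists passed. The median, the mean and camera's direction did not all share a sign for 5 lists, none past the threshold, namely basal keratinocyte, matrix remodelling, AP-1, glycolysis and hair follicle genes.

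**Figure D3:**
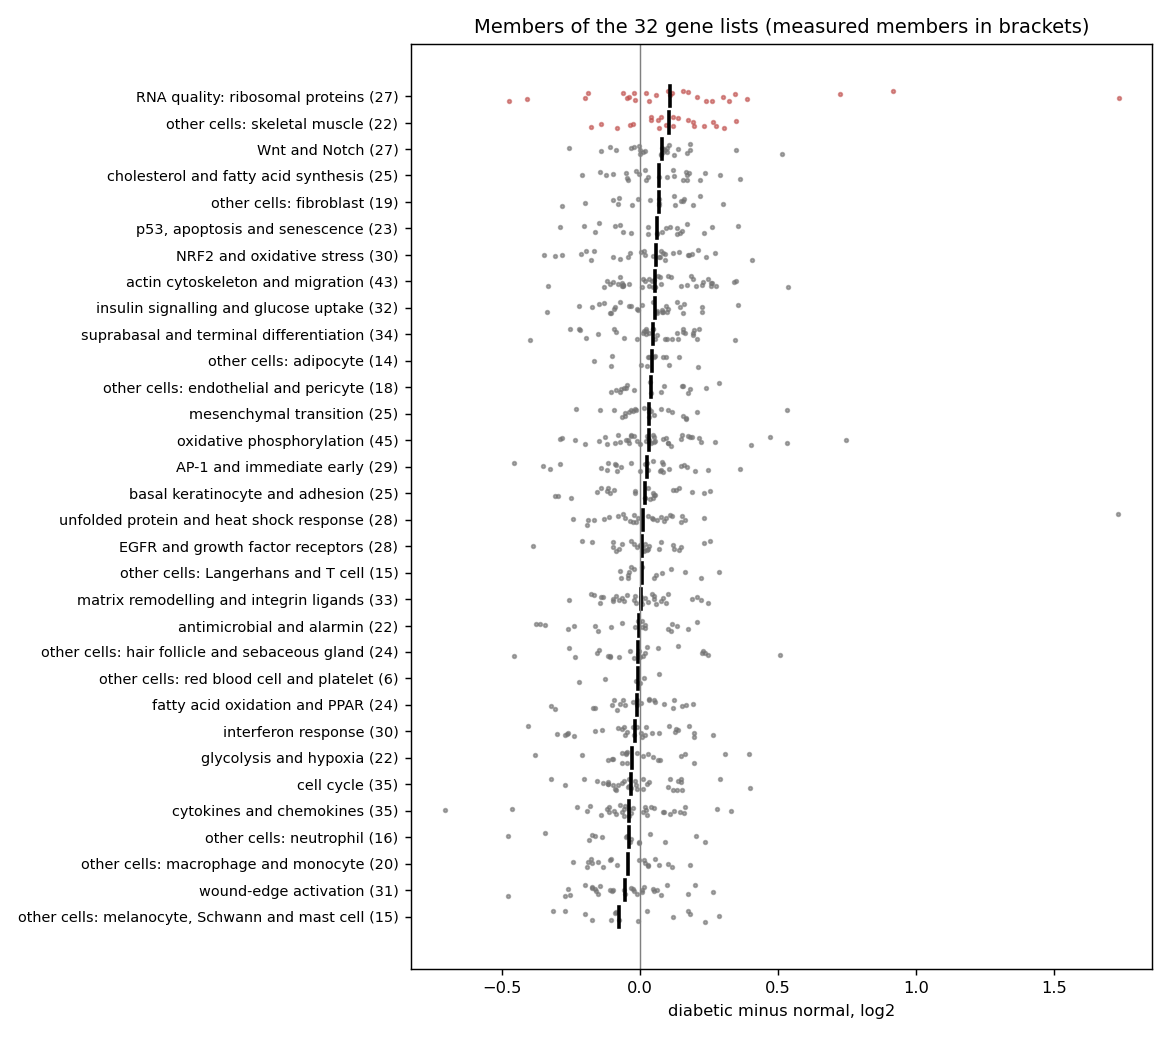
Difference between diabetic and normal samples (log2, horizontal axis) for each measured member of the 32 gene lists (points, spread vertically for visibility) with the list median (black bar), measured members in brackets. The lists past the camera threshold are in red, ribosomal proteins and skeletal muscle, both with a median of 0.11, and all other medians lie closer to 0.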

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

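The tests of 7SL and of the unannotated probe sets were chosen only after the results were seen.

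7SL, the RNA of the signal recognition particle, gave the largest difference found outside the gene test, on probe sets that name both Rn7s1 and Rn7s2 and so were not assigned to a gene. Signal was 9.25, 8.36 and 7.72 on the diabetic arrays and 5.03, 6.29 and 3.49 on the normal arrays, a difference of 3.51 (SE 0.72, 11.4-fold, limma adjusted p 0.821 over all probe sets), and with any 1 array left out it stayed between 2.78 and 4.18, which argues against a single array deciding it. An array-wide difference in RNA amount or integrity could contribute and stays open. As deviations from group means over the 6 arrays, 7SL correlated with 7SK at r = 0.826 (Spearman rho 0.886, r = 0.847 without the 2 arrays farthest from the median, exact one-sided permutation p 0.0278 for r and for rho, the smallest that 36 arrangements can give) and with the RNase P RNA gene Rpph1 at r = 0.937. Over all 8 noncoding RNAs looked at that lay above the background limit on every array, correlations ran from -0.099 (Vaultrc5) to 0.937, 7 above 0, and the median was 0.455 (exact one-sided permutation p 0.111, and 0.111 for 7SK and Rpph1 after adjustment over the 8), and Rpph1 differed between groups by 0.68 (SE 0.40), so neither this nor a rise of 7SL with diabetes is excluded.

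Probe sets outside the annotation table held many of the small p-values. The unannotated probe set 10343148 differed by -1.11 (SE 0.09), at 0.74, 0.70 and 0.73 on diabetic and 1.87, 1.91 and 1.72 on normal arrays, all under the background limit, with a limma adjusted p of 0.215 over all probe sets. Of the 40 smallest p-values in that fit, 35 belonged to unannotated probe sets, and 9.02% of these probe sets had an unadjusted p under 0.05 against 3.75% of single-gene probe sets. A variance prior shared with steadier probe sets could account for part of this, since the median within-group SD was 0.27 against 0.15 and the percentage was 6.17% when they were fitted on their own. What these probe sets measure is not known here, control probe sets could be among them, and chance stays open for the rest, as 10 splits of the arrays are too few for a share under 0.05 (749 such probe sets in the real split, 650 in the highest other).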

How the results depend on the processing

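The restriction to genes above the background limit, the separate fit of unannotated probe sets and the ribosomal list without Rpl5 were chosen after seeing the data. The count of genes past the adjusted threshold was 0 in all 15 settings that kept every array, with smallest adjusted p from 0.0948 to 0.689, and 0 to 2 with 1 array left out. The count at an unadjusted p under 0.05 and a fold of at least 1.5 (51) stayed within 1.5 times in 10 of 13 such settings. It was 18 without variance moderation, 970 at a fold of 1.2 and 11 at a fold of 2, and 57 to 109 with 1 array left out. The count of gene lists (2) was 1 after quantile normalization, 1 without the lower 50% of genes by mean and 1 among genes above the limit. It was 0 with an estimated correlation, 0 in rank-based camera, 0 to 2 with 1 array left out, and 0 in fry, which asks a different question (a list against no change, not against other genes). The ribosomal list was past the threshold in 14 of 18 settings (adjusted p 0.00156 to 0.421, and 0.0258 without Rpl5) and the muscle list in 8 of 17 (0.00769 to 0.443), and both kept their direction in all of these. The 2 eBayes settings are not counted here, as camera does not use that fit. Fewer genes or arrays entered the filtered and left-out fits, and the estimated correlation came with fewer degrees of freedom. For the other settings the cause was not tested. Of 41 named genes at most 4 changed sign in any setting, and 1 passed in 1 setting, Rpl5 without diabetic replicate 3.

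With replicate number as a replicate block, 0 genes passed, 54 genes met the unadjusted p and fold, and 2 lists passed. Deviations of same-numbered arrays correlated at -0.018, 0.0078 and 0.014 across genes, which gave no sign of a pairing. As 51.5% of genes were above the background limit on no array, a pairing seen only in expressed genes could be missed.

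Signal over background also limits these comparisons. The median gene mean was 1.81, under the background limit of every array (1.98 to 2.12) and above the receptor medians (1.34 to 1.45).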

Other observations

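The tests and gene groups in this part were chosen only after the results were seen, except the lists, the count at a fold of 1.5 and the count past the adjusted threshold.

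Most of the structured and nuclear RNAs looked at had higher signal in diabetic samples, by widely different amounts, and no test of them as a group was run. Beside 7SL, 7SK, Rny1 and Rmrp, the telomerase RNA gene Terc was at 2.18 ± 0.05 (SD) in diabetic and 1.78 ± 0.28 in normal samples, a difference of 0.41 (SE 0.14, limma adjusted p 0.812), above the background limit on all 3 diabetic and 0 normal arrays. The spliceosomal U6 gene Rnu6 went the other way, by -0.78 (SE 0.18, limma adjusted p 0.780), at 0.92 ± 0.06 and 1.70 ± 0.46, above the limit on 1 normal array alone. Other structured RNAs gave smaller or less certain differences, the Y RNA gene Rny3 by 0.19 (SE 0.48), the vault RNA gene Vaultrc5 by 0.10 (SE 0.66), Rnu12 by 0.16 (SE 0.15) and Rpph1 by 0.68 (SE 0.40). The nuclear RNA Malat1 was at 5.75, 2.59 and 2.99 on the diabetic and 2.42, 2.65 and 2.67 on the normal arrays. None passed the adjusted threshold.

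Of the gene families looked at, olfactory and vomeronasal receptor genes lay lower in diabetic samples, with a median of -0.06 over 1194 genes, 26 higher and 99 lower at an unadjusted p under 0.05 (camera adjusted p 0.00113 over 7 families, adjusted p = 0.206 with an estimated correlation). Keratin-associated protein genes of the hair shaft had a median of -0.08 over 44 genes (camera adjusted p 0.0473, adjusted p = 0.206 with an estimated correlation). The 52 keratin genes had a median of -0.02 (camera adjusted p 0.224) and 31 histone genes 0.02 (0.188). The 300 microRNA genes had a median of -0.04 (0.0853) and the 51 small nucleolar RNA genes 0.00 (0.133). The 68 genes of the Rpl and Rps name pattern, which also admits kinase genes, had a median of 0.02 (0.0473, and adjusted p = 0.206 with an estimated correlation). Differences followed brightness slightly, from a median of -0.04 among the dimmest 20% of genes to 0.03 among the brightest.

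The ribosomal protein and skeletal muscle lists were the only lists past the camera threshold, and neither passed with an estimated correlation (adjusted p = 0.421 and adjusted p = 0.443). The ribosomal median lay at percentile 99.32 and the muscle median at percentile 99.31 of random lists matched on mean level. Both lists were singled out by camera on these same differences, and the uncalled cholesterol and fatty acid synthesis list reached percentile 98.2. These percentiles therefore cannot decide whether a brightness-dependent difference between the arrays was the whole cause of the higher medians. After quantile normalization both lists stayed higher, with a camera adjusted p of 0.0334 for the ribosomal and 0.0742 for the muscle list. The values without it were 0.00490 and 0.0226. Skeletal muscle in the captured area may account for the muscle list and stays open. The 8 members above the background limit on all arrays exceeded the other 14 by 0.077 on average (exact permutation p 0.223, two-sided, 319770 arrangements), and the bright members Tnni2, Tnnc2 and Ckm differed by 0.23, -0.02 and 0.12. A difference in RNA amount or integrity stays open for the ribosomal list, which was fixed to follow RNA quality, and was not tested for it. Diabetes itself also stays open for both lists, how many of the muscle genes (0 of them in another list) keratinocytes express was not tested, and capture by E-cadherin staining would leave muscle out unless it adjoined the tongue.

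The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2 lists and the highest other split 0, so 1 of the 10 reached that count. For genes at an unadjusted p under 0.05 and a fold of at least 1.5, the real split gave 51 and the highest other 50, and at a fold of at least 2 it gave 11 against 9. The shared direction of those 11 does not set the real split apart, since 9 of 9, 7 of 8 and 6 of 6 genes went the same way in other splits. For genes past the adjusted threshold all 10 splits gave 0.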
